A study of Mus musculus with 536 samples.

How the data were processed

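Globin-reduced RNA from peripheral blood of C57BL/6 mice, drawn after a single total body dose of gamma radiation or none, had been hybridised to 536 Affymetrix mouse arrays. Per the submitters' processing notes the values came from RMA in the affy package, with no version or settings given. The deposited values are log2 signals per probe set, as the authors wrote them (2.17 to 14.85 over the table, array medians 5.61 to 5.93). The notes do not say whether the arrays of the batches were normalised together. No raw intensities were used, so background correction and summarisation are the authors' own. The number of arrays per group limits the precision.

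The table held 22690 probe sets. The 64 control probe sets, 1555 with no gene symbol and 691 with several were left out, because they stand for no single gene. The other 20380 were assigned to 12393 genes by the symbols that the table of the array's probes gives, with the Entrez identifier of 29 probe sets unmatched in the mouse reference. For the 4956 genes with several probe sets, the probe set with the highest mean over all arrays stood for the gene. Every array of the table was used. The labels put the arrays in 4 sets (240, 226, 50 and 18 mice in 48, 48, 9 and 4 groups). For 2 mice of the dose-time set a repeat scan was averaged with the first. The differences between the scans of a mouse had an SD of 0.25 and 0.21 over genes, against a median of 0.56 and 0.51 to other mice of the group.

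Each set was fitted on its own with a group-means model in limma 3.58.1 under R 4.3.3 (with data.table, version 1.17.8), so that all groups of a set shared an estimate of the spread (192, 178, 41 and 14 residual degrees of freedom). A dose trend is the least-squares slope of the group means on dose per 100 cGy at a given time and agent, averaged over both sexes in the sex and treatment set. Differences of slope between times (moderated F test), agents and sexes, and differences between agents or sexes at 0 cGy, were contrasts of the same fits, with empirical Bayes moderation and Benjamini-Hochberg adjustment over genes. The threshold was an adjusted p of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 18 fixed lists of a comparison, and again with an estimated correlation and with array run as a block. A gene list score is the mean log2 value of its genes relative to the 0 cGy mice. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

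The groups, tests, gene lists, alternatives and rule for naming genes were set before the data were examined. For each trend the rule took the 8 rising and 8 falling genes with the largest fold at 600 cGy among those past the threshold with 1 sign at every dose. For each agent, sex or 150 cGy comparison it took the 8 and 8 with the largest fold, and for each slope difference the 5 and 5 largest. It always took Cdkn1a, Bax, Mdm2, Ccng1, Phlda3, Eda2r, Cd79a, Ms4a1, Cd3e, S100a8, Alas2, Pf4 and the sex-linked genes Xist, Eif2s3y, Kdm5d and Uty, and per list up to 4 members with the smallest p. Bax and Eda2r were not analysed here, since no probe set carried their symbols. Alb was singled out after its values were seen. The fixed lists were p53 targets, cell cycle, interferon response, NF-kB and inflammatory, JAK-STAT feedback, immediate early and stress, MHC class II, B cell, T cell, NK cell, mature neutrophil, immature neutrophil granule, monocyte, erythroid and reticulocyte, globin, platelet and megakaryocyte, eosinophil, basophil and mast cell, and plasma cell. The added lists, for hepatocytes, tissue macrophages, cardiomyocytes, endothelium, lung epithelium and chemosensory receptors, were written after the data had been seen and were adjusted among themselves.

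The titles carry a mouse number and a code in brackets. The middle part of the code was taken to be the array run, which the titles do not state. Values given by run and array run as a block rest on this reading. Mice with the same number in different groups had residuals with a mean correlation of 0.02 in the dose-time set, 0.04 in the sex and treatment set, 0.06 in the small treatment set and -0.13 in the small 7 day set. The numbers were therefore not taken to pair mice. In the dose-time set each of the 5 runs held 1 mouse of every group, which lets a difference be read within each run.

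The alternatives were array run as a block, mouse number as a replicate block, only the groups of the comparison in the fit, dim genes left out (mean under the 30th percentile), the mean of a gene's probe sets and quantile normalisation within a set. Others were centring each array on its median, a trended and robust prior, array weights and dose on a log2 scale. The last were the F test over the 7 differences from 0 cGy, the first scan alone, genes with a log2 fold of at least 0.5, and leaving out 1 mouse of every group in turn. The leaving out took 5 fits, for the first 5 mice of a group by array run in the dose-time set and by mouse number elsewhere. Groups of under 5 mice lost none in some of these fits, and larger groups kept the mice past the first 5 in all. The 0 cGy untreated mouse 10 of the small treatment set was thus always kept. Added after the data had been seen were a hepatocyte score as a covariate, leaving out arrays with Alb of 10 or more, and the spread of an array as a covariate. So were leaving out the 800 cGy mice at 24 hr, leaving out the female mouse 5 at 300 cGy and 6 hr and, in the small treatment set, leaving out the 0 cGy untreated mouse 10. For each comparison the mice were also split at random 100 times, the real split included.

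The fits were tested on simulated data with the same group sizes, in which 200 of 12393 genes were changed. Slopes of 0.1 per 100 cGy were recovered for 92 to 96% of the changed genes in the dose-time set, 58 to 67% in the sex and treatment set and 67% in the small treatment set. Slopes of 0.3 were recovered for 98 to 100% in all of them. Slope differences of 0.1 were recovered for 30 to 41% and of 0.3 for 96 to 100% in the sex and treatment set. Group differences of 0.5 were recovered for 36 to 51% and of 1.5 for 98 to 100%, and in the small 7 day set differences of 1 for 75% and of 2 for 97%. Camera found 26 of 26 shifted lists and 1 list that had not been shifted. The simulated noise was independent between genes, so neither these shares nor the few false calls cover genes that vary together. A warning that a tolerance was not reached came up once while array weights were estimated.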

Results

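Transcript levels in peripheral blood of C57BL/6 mice were measured on 536 arrays after a single total body dose of gamma radiation or none. The mice formed 4 sets. The dose-time set held 240 mice in 48 groups of 5, one group for each of the doses 0, 100, 200 or 300 cGy and 450, 600, 800 or 1050 cGy at 6, 24, 48, 72, 120 and 168 hr. The sex and treatment set held 226 mice in 48 groups of 3 to 5, female (111) or male (115). They had been given granulocyte colony-stimulating factor (GCSF, a cytokine that drives neutrophil production), lipopolysaccharide (LPS, a bacterial wall component that triggers inflammation) or neither. Their doses were 0, 200, 300 or 600 cGy and their times 6 or 24 hr. The small treatment set held 50 mice in 9 groups of 5 to 6 (GCSF, LPS or neither, at 0, 150 or 600 cGy, all at 6 hr). The small 7 day set held 18 mice, of which 10 had received 150 cGy 168 hr earlier and 3 were their 0 cGy controls at 168 hr. The number of arrays per group limits the precision of every value. The labels give no sex outside the sex and treatment set and do not state when the agents were given.

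The comparisons asked how blood transcripts changed with dose and time, and how sex, GCSF and LPS altered these changes. The values of a gene are log2 differences between 600 and 0 cGy with the standard error of the fitted model. The words "rose" and "fell" mean that the gene's slope on dose over all doses at that time passed an adjusted p of 0.05 in limma among 12393 genes. Numbers of genes up and down describe the calls of a fit and not a direction of the blood as a whole, because the larger of the directions turned under at least 1 alternative in 20 of 25 comparisons. Bax and Eda2r were not analysed here. The Entrez identifiers that the files give are 12575 for Cdkn1a, 27280 for Phlda3, 12482 for Ms4a1, 11656 for Alas2, 56744 for Pf4 and 11657 for Alb.

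At 6 hr after irradiation, B cell transcripts fell and transcripts of mature neutrophils, of cytokine signalling and of the p53 pathway rose. The largest falls were in the B cell genes Pou2af1 (-5.12 ± 0.54) and Cd79b (-4.92 ± 0.49), in B3gnt5 (-5.09 ± 0.38), in the immunoglobulin segment Ighv14-2 (-4.80 ± 0.48) and in Ms4a1 (-4.74 ± 0.48), which encodes the surface protein CD20. Ms4a1 stood at 11.80 ± 0.16 (SD, n = 5) at 0 cGy and at 7.06 ± 0.73 (SD, n = 5) at 600 cGy, and it was lower in each of the 5 array runs (-5.52 to -3.89). Of 21 measured B cell genes 20 fell and none rose, with Cd22 at -3.54 ± 0.32 and Cd72 at -2.81 ± 0.26. All 8 MHC class II genes fell (median -3.49), among them H2-Ab1 at -4.26 ± 0.39 and H2-Aa at -4.14 ± 0.37. Of 23 T cell genes, 17 fell and 1 rose, with Thy1 at -3.21 ± 0.45 and Cd28 at -1.85 ± 0.31, and 9 of 16 NK cell genes fell, with Klrd1 at -1.58 ± 0.33. The largest rises were in Lrg1 (4.42 ± 0.42), Lcn2 (4.11 ± 0.58), Socs3 (3.77 ± 0.24), Il1r2 (3.64 ± 0.40) and Mmp8 (3.64 ± 0.42). Of 18 mature neutrophil genes 16 rose and none fell (median 1.99), with Hcar2 at 2.38 ± 0.26.

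Of 36 p53 targets, which answer DNA damage, 23 rose and 3 fell at 6 hr. Cdkn1a, the inhibitor of cyclin-dependent kinases, rose by 2.02 ± 0.31 (adjusted p = 1.63e-07) from 6.74 ± 0.09 (SD, n = 5) at 0 cGy, in 5 of 5 runs (1.68 to 2.26). Fas rose by 1.31 ± 0.17, Ccng1 by 1.32 ± 0.23, Phlda3 by 1.10 ± 0.19 and Mdm2 by 0.39 ± 0.18, while Sesn1 fell (-1.87 ± 0.24). Of 30 interferon genes 21 rose (Ifit3 2.40 ± 0.39, Oas2 1.41 ± 0.21). Of 31 NF-kB and inflammatory genes 16 rose and 2 fell (Clec4e 3.01 ± 0.34, Il1rn 2.99 ± 0.41), of 17 JAK-STAT feedback genes 11 rose (Cebpd 2.58 ± 0.32). Among 24 immediate early genes 10 rose and 4 fell, with Ier3 at 3.17 ± 0.28. Among immature granule genes, 4 rose and 1 fell of 13, with Ngp at 1.51 ± 0.33 and Serpinb1a at -2.91 ± 0.35. Within the cell cycle list 3 genes rose and 4 fell of 38, with Pcna at -1.55 ± 0.22. The monocyte list had 3 risen and 5 fallen of 18, the plasma cell list 1 and 2 of 8, and the eosinophil, basophil and mast cell list 1 and 2 of 12. No member of the erythroid (27 genes), globin (6) or platelet (18) lists passed, with Alas2 at -0.03 ± 0.56 (adjusted p = 0.875) and Pf4 at 0.32 ± 0.13 (adjusted p = 0.626). Xist, transcribed from the inactive X chromosome, fell (-1.77 ± 0.22).

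In all, 2004 genes rose and 2297 fell at 6 hr in limma, and with 1 mouse of every group left out in turn the total of 4301 ranged from 2801 to 4786. Adjusted over the list alone, 23 p53 targets rose and 3 fell, 20 B cell genes fell, 16 mature neutrophil genes rose, 23 interferon genes rose, and 1 T cell gene rose with 19 fallen. The camera test moved the B cell list down (adjusted p over 18 lists = 1.44e-26) and the mature neutrophil list (3.04e-25), JAK-STAT (3.78e-11), interferon (2.61e-12), NF-kB (5.55e-08) and p53 (8.84e-06) lists up. Over all times of the dose-time set, the calls that held with an estimated correlation were those of 6 hr for B cell (0.0018), MHC class II (0.00361), mature neutrophil (0.0018), JAK-STAT (0.0018), NF-kB (0.00361), p53 (0.00648) and interferon (0.0224) lists. The T cell and NK cell calls at 6 hr (adjusted p = 2.05e-08 and 0.00138) did not hold (adjusted p = 0.131 and 0.412 with an estimated correlation). Nor did those of the immediate early (0.00773, then 0.184) and immature granule lists (0.0313, then 0.131).

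At 24 hr the lymphocyte genes were still lower, and platelet genes had begun to rise. Ighv14-2 fell (-5.10 ± 0.48), the IgE receptor gene Fcer2a (-3.54 ± 0.29), Cd22 (-3.11 ± 0.32), the chemokine receptor gene Ccr7 (-3.07 ± 0.41) and Cd55 (-3.04 ± 0.25). All but 1 of the 21 B cell genes fell (20, median -2.29), as did all 8 MHC class II genes (H2-Oa -2.91 ± 0.31) and 16 of 23 T cell genes (Cd8b1 -3.74 ± 0.48, Cd3g -2.98 ± 0.43, Cd3e -1.50 ± 0.31). The scavenger receptor gene Marco rose by 2.92 ± 0.54, Cdkn1a by 2.75 ± 0.31 (adjusted p = 1.51e-04, higher in 5 of 5 runs, 0.56 to 3.94), Rhoc by 2.26 ± 0.27 and Phlda3 by 2.10 ± 0.19. Of 18 platelet genes 17 rose (median 1.11), with Gp1bb at 1.41 ± 0.30, Thbs1 at 1.65 ± 0.30 and Pf4 at 0.70 ± 0.13. The p53 list went both ways (6 rose, 7 fell), with Ddb2 at -1.41 ± 0.19, and its Mdm2 (0.18 ± 0.18, adjusted p = 0.776) and Ccng1 (1.37 ± 0.23, adjusted p = 0.0603) did not pass. In the erythroid list 14 genes rose, although its median was -0.01, its mean 0.13 and its camera call up (9.60e-04, and 0.726 with an estimated correlation).

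The 24 hr count was 4798 genes (2342 up, 2456 down) in limma and ranged from 1981 to 6069 with 1 mouse of every group left out. Centring each array on its median turned the balance to 3141 up and 2176 down. Mice of the higher doses varied at this time. In the mice labelled 800 cGy, B cell scores relative to the controls were -0.94 to -1.58 in 4 of the 5 and -3.20 in the fifth. Their erythroid scores were 0.33 to 1.33 in all 5, which bears on the erythroid calls above. Those of the 450 cGy mice were -1.25 to 0.13 and of the 1050 cGy mice -2.31 to 0.16. The 600 cGy mice, at -0.27 to 0.63, overlapped with the 800 cGy mice. In the same 4 mice as for B cells, the T cell scores (-0.11 to 0.09) lay above those of all 450 cGy mice (-1.81 to -0.29). At 1050 cGy, mice 2 and 4 had B cell scores of -0.55 and -0.70, above every 800 cGy mouse, and p53 scores of 0.49 and -0.07. At 600 cGy, mouse 5 had a B cell score of -1.43 and a p53 score of -0.10. Without the 800 cGy mice 3578 genes passed (1551 up, 2027 down). A moderated F test over the 7 differences from 0 cGy, which needs no monotonic change, called 7360 genes. With array spread as a covariate 2341 passed, and 3045 without arrays whose Alb was 10 or more. The camera calls of the B cell (6.16e-18), MHC class II (4.51e-09), T cell (1.78e-08) and platelet (1.51e-08) lists were lost with an estimated correlation (adjusted p = 0.0528, 0.105, 0.277 and 0.272).

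From 48 to 72 hr, reticulocyte and red cell transcripts fell with dose while Cdkn1a, Phlda3 and many platelet and macrophage genes rose. At 72 hr Alas2, the first enzyme of haem synthesis in red cell precursors, fell (-4.59 ± 0.56, adjusted p = 7.05e-24) from 14.25 ± 0.04 (SD, n = 5), lower in 5 of 5 runs (-6.73 to -2.00). Its 0 cGy level lies near the top of the scale (14.85), so the fall may be larger than this value. Slc25a37 and Fech, which bring iron into haem, fell at 48 hr (-4.53 ± 0.45 and -3.69 ± 0.43) and further at 72 hr (-5.22 ± 0.45 and -4.94 ± 0.43). At 72 hr Bpgm (-5.56 ± 0.52), Car2 (-4.33 ± 0.44) and the globin gene Hbb-b2 (-4.71 ± 0.50) were lower as well. Of 27 erythroid genes 19 fell and 4 rose at 48 hr, and 22 fell and 4 rose at 72 hr (median -2.07). Proliferation genes fell with them: 21 of 38 cell cycle genes at 48 hr (Ccna2 -3.05 ± 0.29) and 23 at 72 hr (Ube2c -5.36 ± 0.49), and Nusap1, which binds the mitotic spindle, fell (-5.98 ± 0.46 and -5.90 ± 0.46). Cdkn1a rose by 3.46 ± 0.31 at 48 hr and 4.19 ± 0.31 at 72 hr, and Phlda3 by 1.95 ± 0.19 and 2.37 ± 0.19, each in 5 of 5 runs. The p53 list nevertheless had genes on both sides (17 rose and 7 fell at 48 hr, 17 and 10 at 72 hr).

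Platelet genes rose further, 14 with 2 fallen at 48 hr and 16 of 18 with none fallen at 72 hr (median 2.42): Vwf by 3.78 ± 0.37, Selp by 3.35 ± 0.35 and Itga2b by 3.12 ± 0.28. Mature neutrophil genes rose again at 48 hr (16 of 18), with Pglyrp1 at 2.62 ± 0.31 and Csf3r at 2.35 ± 0.32, and 13 rose at 72 hr, when S100a8 fell (-2.18 ± 0.49) in 5 of 5 runs. At 72 hr the largest rises were in Gstt1 (6.21 ± 0.54), Alox15 (4.89 ± 0.70), the complement genes C1qb (4.62 ± 0.83) and C1qa (4.31 ± 0.74), Cfp (4.22 ± 0.54) and Vsig4 (4.19 ± 0.75). In all 10 of 14 genes of a tissue macrophage list rose. Interferon genes parted: Irf7 (-3.12 ± 0.32) and Rsad2 (-3.32 ± 0.36) fell, while Igtp rose by 2.21 ± 0.20. Lymphocyte genes stayed lower, with 19 B cell and 17 T cell genes fallen at 72 hr (Fcer2a -2.86 ± 0.29, Cd3g -2.45 ± 0.43).

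In limma, 5865 genes passed at 48 hr (2977 up, 2888 down) and 6622 at 72 hr (3263 up, 3359 down). The camera calls at 72 hr for the erythroid (2.28e-09), platelet (2.28e-09), B cell (2.34e-09) and cell cycle (3.71e-05) lists gave an adjusted p of 0.249 with an estimated correlation in each of these lists. At 48 hr the p53 (0.00929) and mature neutrophil (3.50e-11) calls gave adjusted p = 0.198 and 0.101 with an estimated correlation. For NK cell genes at 72 hr (6 rose, 7 fell) the median was above 0 and the camera direction down (adjusted p = 0.484).

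**Figure D1:**
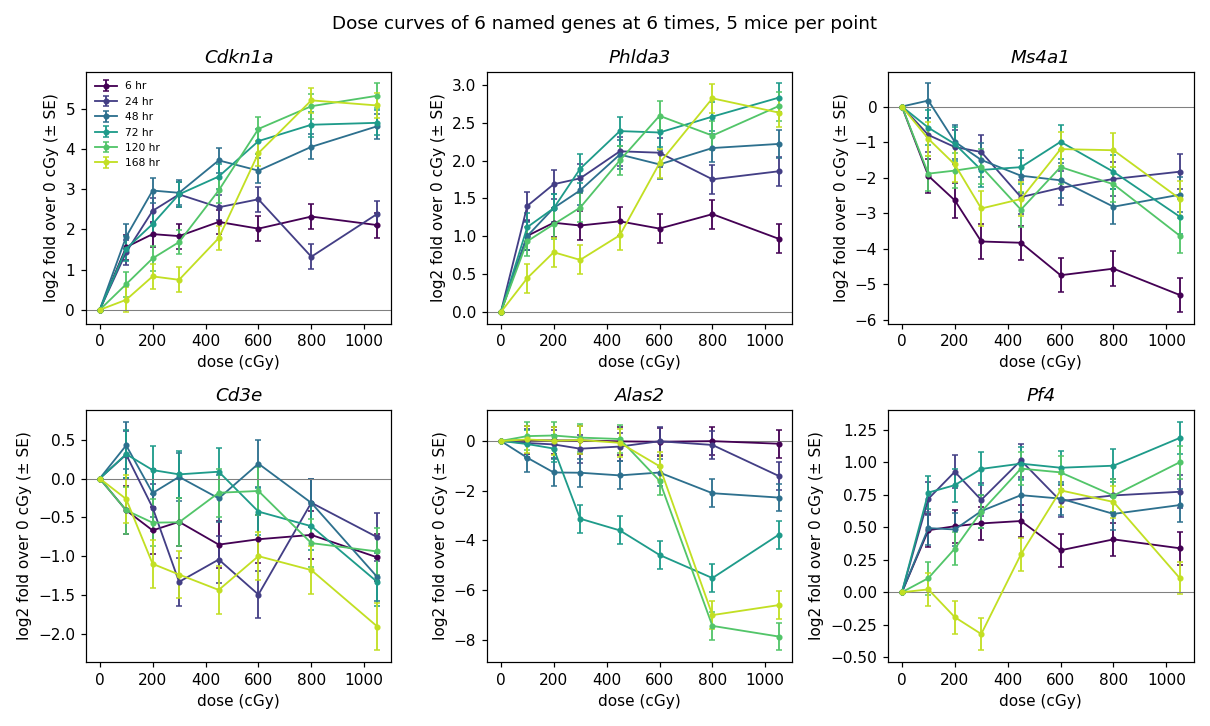
Log2 difference from the 0 cGy mice of the same time (vertical axes) by dose in cGy (horizontal axes) for Cdkn1a, Phlda3, Ms4a1, Cd3e, Alas2 and Pf4 in the dose-time set, with group means of 5 mice as points, standard errors as bars and one line per time. Cdkn1a at 600 cGy is 2.02 at 6 hr and 4.49 at 120 hr, and Alas2 is -4.59 at 72 hr.

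At 120 and 168 hr liver transcripts rose steeply, and B cell genes were still lower. Apoa2 rose by 7.77 ± 1.49, Apoa1 by 7.45 ± 1.39, Rbp4 by 6.82 ± 1.35 and Cyp2e1 by 6.59 ± 1.31 at 120 hr. Serpina1b rose by 9.38 ± 1.69, Apoc3 by 9.35 ± 1.60, Hamp by 8.68 ± 1.37 and Hpx by 8.23 ± 1.41 at 168 hr. All 24 measured genes of a hepatocyte list rose at both times (median 6.65 and 7.62). The list was written after the values were seen, as were the 5 other added lists. Tissue macrophage genes rose beside them, 11 of 14 at 120 hr and 12 at 168 hr, with Folr2 at 2.36 ± 0.28 and Mertk at 2.44 ± 0.39, and Gstt1 rose by 8.51 ± 0.54 at 120 hr. Cdkn1a remained high at 4.49 ± 0.31 and 3.89 ± 0.31, in 5 of 5 runs at each time, and Phlda3 at 2.59 ± 0.19 and 1.97 ± 0.19. Of the p53 targets 23 rose and 9 fell at 120 hr, and 21 rose and 10 fell at 168 hr, with Gadd45a at -2.08 ± 0.27.

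Fcer2a (-4.53 ± 0.29 at 120 hr and -4.32 ± 0.29 at 168 hr), Ighv14-2 (-5.21 ± 0.48 and -4.83 ± 0.48) and Rpl22l1 (-6.56 ± 0.60 and -4.75 ± 0.60) fell. Of 21 B cell genes 20 fell at 120 hr and 18 at 168 hr, and of 23 T cell genes 19 and 22 (Cd8b1 -3.33 ± 0.48, Il7r -3.15 ± 0.43). In the erythroid list 22 genes fell at 120 hr and 24 at 168 hr, with Alas2 at -1.60 ± 0.56 and -1.02 ± 0.56 and Epb42 at -2.18 ± 0.40. The neutrophil calgranulins S100a8 and S100a9 fell (-3.38 ± 0.49 and -5.31 ± 0.59) at 120 hr, whereas the primary granule gene Prtn3 rose by 4.32 ± 0.42. Platelet genes went from 14 risen and 3 fallen at 120 hr to 4 risen and 13 fallen at 168 hr (Cavin2 -2.94 ± 0.25), and Pf4 stayed up at 0.78 ± 0.13.

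In limma 10208 genes passed at 120 hr (4387 up, 5821 down) and 10182 at 168 hr (4405 up, 5777 down). With array spread as a covariate more genes rose than fell at both times (3913 up and 3252 down, then 4176 up and 3336 down). None of the camera calls at these times held with an estimated correlation: hepatocyte at 168 hr moved from 6.11e-08 to 0.41, erythroid from 2.42e-13 to 0.251 and B cell from 4.08e-04 to 0.656. The test and the median differed in sign for the cell cycle list, which moved down with medians of 0.20 at 120 hr and 0.21 at 168 hr (means 0.05 and 0.21). The platelet list at 168 hr moved down too, with a median of 0.46 and a mean of 0.28.

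The liver transcripts were not spread evenly over the mice. Alb stood at 5.84 ± 0.31 (SD, n = 5) in 0 cGy mice at 6 hr and at 14.55 ± 0.29 (SD, n = 5) after 1050 cGy at 168 hr. It was at least 10 in 1 of 40 mice at 6 hr, 23 of 40 at 24 hr, 26 of 40 at 48 hr and 21 of 40 at 72 hr, doses of 0 cGy included. At 120 and 168 hr it was at least 10 in 30 of 30 mice given 600 cGy or more (13.53 to 14.79) and in 5 of 40 mice given 300 cGy or less (4.92 to 13.47). So it was in 5 of 5 mice given 450 cGy at each of these times. Without the arrays at 10 or more no mice above 300 cGy are left at these times, and a trend over 0 to 300 cGy called 5074 genes at 120 hr and 9739 at 168 hr.

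**Figure D2:**
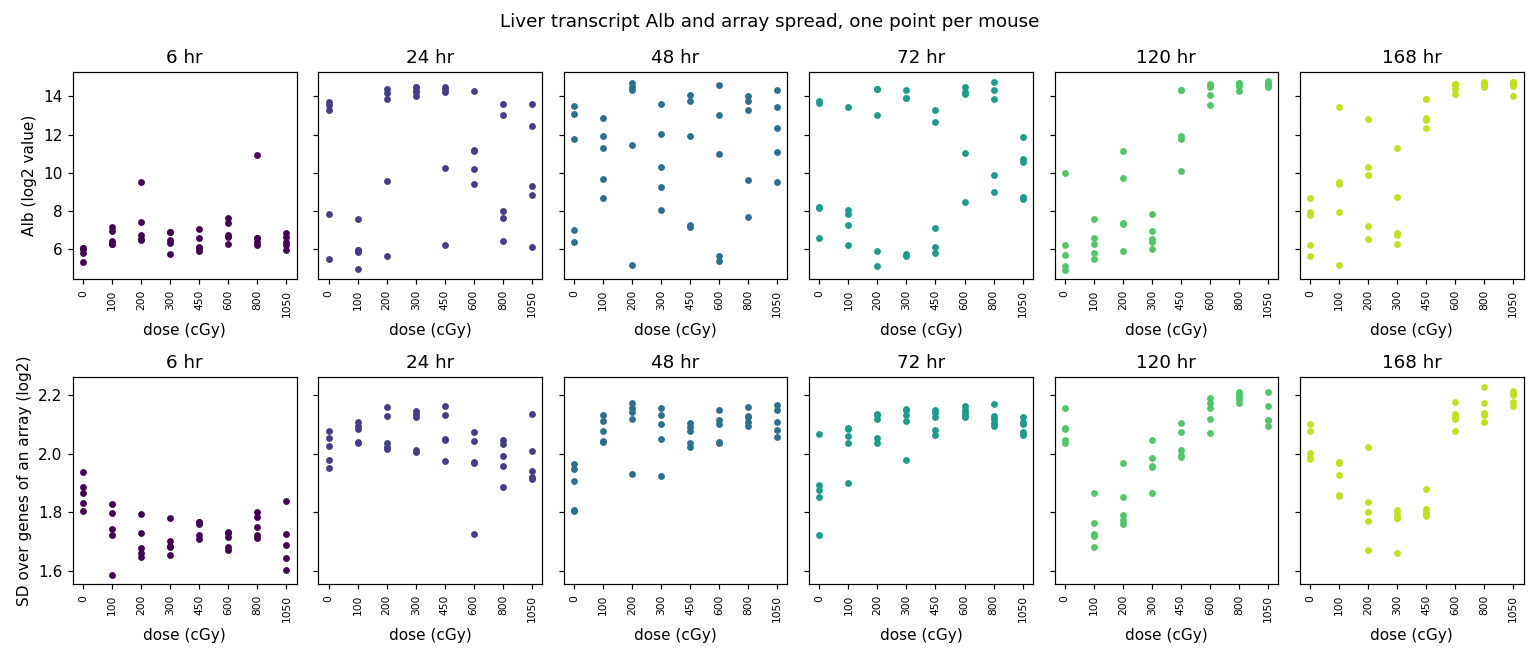
Log2 level of Alb and standard deviation of all genes' log2 values within an array (vertical axes) by dose in cGy and time in hr in the dose-time set, one point per mouse. At 120 and 168 hr the 30 mice given 600 cGy or more lie between 13.53 and 14.79 for Alb.

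The effect of dose differed between times for 11443 of 12393 genes in the moderated F test. From 6 to 168 hr the slope per 100 cGy rose by 1.03 ± 0.17 for Apoc3, 0.97 ± 0.12 for Fgb and 0.44 ± 0.03 for Cdkn1a. It fell for S100a9 (-0.93 ± 0.06), for S100a8 (-0.74 ± 0.05), for Tent5c (-0.80 ± 0.05), for Alas2 (-0.73 ± 0.06) and for Nusap1 (-0.68 ± 0.05), while the slope of Cd3e (-0.07 ± 0.03) did not pass (adjusted p = 0.0527). The median of the B cell list was already -1.74 at 100 cGy and 6 hr and reached -3.00 at 1050 cGy. The mature neutrophil median climbed from 0.14 at 100 cGy to 2.00 at 450 cGy at 6 hr and was flat beyond. The erythroid and reticulocyte list changed sign with dose at the late times. Its median at 168 hr was 1.18, 1.52, 1.83 and 1.84 at 100 to 450 cGy and -0.55, -2.32 and -2.12 at 600 to 1050 cGy. At 72 hr it ran from 0.27 at 100 cGy to -2.38 at 800 cGy.

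The numbers of genes called against 0 cGy were not ordered by dose, with 8834 at 100 cGy, 5069 at 450 cGy and 6204 at 1050 cGy at 120 hr, and 1854, 8457 and 7437 at 168 hr. At 6 hr they were 3713 at 100 cGy, 5934 at 300 cGy, 4643 at 450 cGy, 4332 at 800 cGy and 6410 at 1050 cGy. The spread of values within an array also differed between groups. At 120 hr it was 2.08 at 0 cGy, 1.75 at 100 cGy and 2.04 at 450 cGy, and at 6 hr 1.87 at 0 cGy against 1.70 to 1.75 in the irradiated groups. Of 64 genes of chemosensory receptors (smell and taste) 54 fell and 2 rose with dose at 120 hr.

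**Figure D3:**
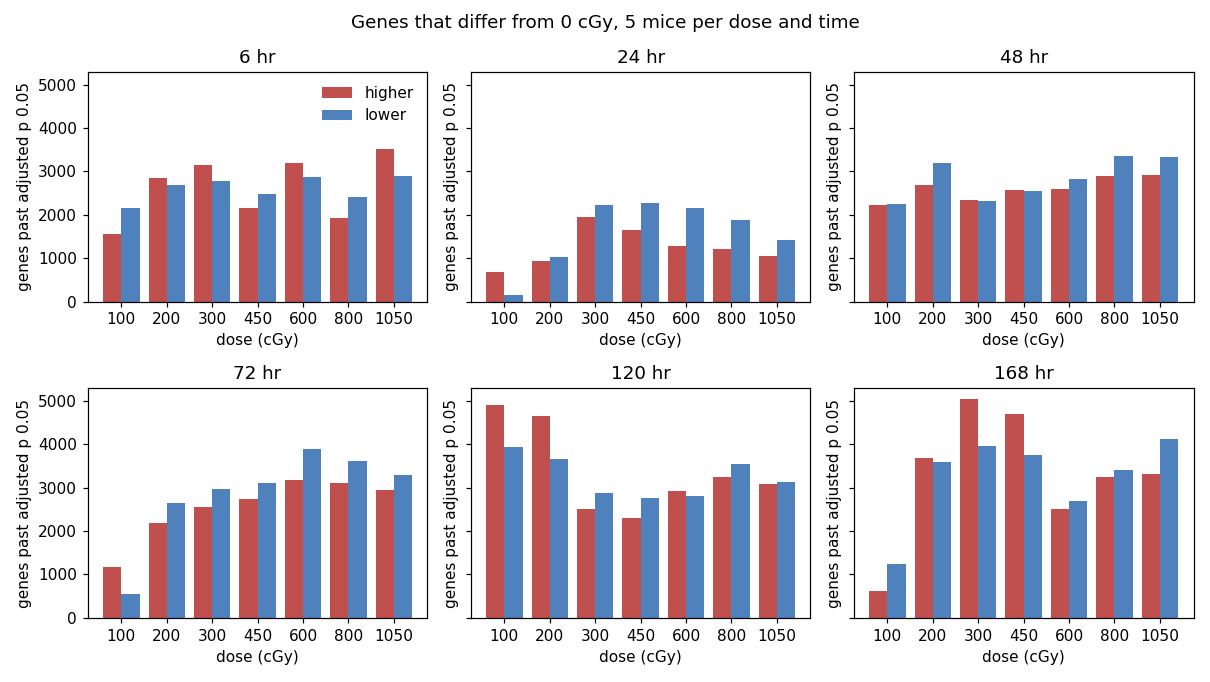
Number of genes past an adjusted p of 0.05 against the 0 cGy mice of the same time (vertical axis) by dose in cGy (horizontal axis), one panel per time in the dose-time set; red bars are genes that stood higher and blue bars genes that stood lower. At 120 hr the count is 8834 at 100 cGy and 5069 at 450 cGy.

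**Figure D4:**
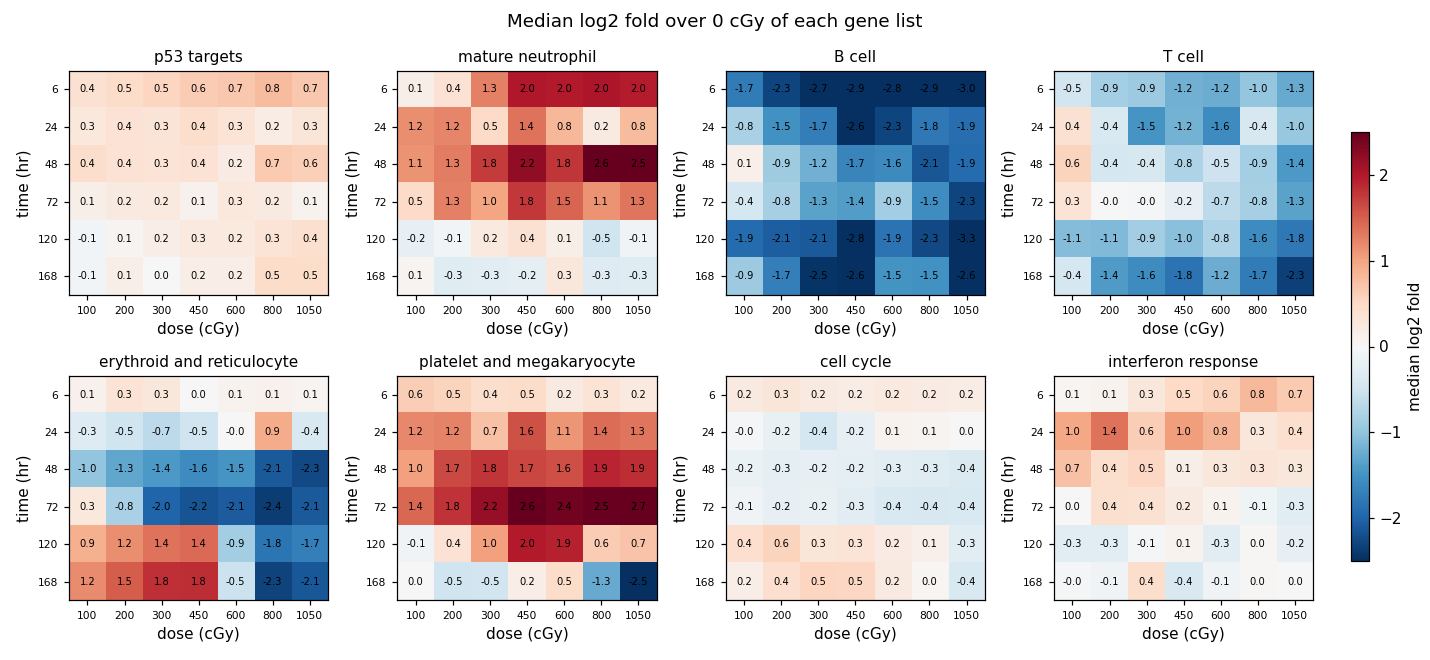
Median log2 difference from 0 cGy (colour) of 8 gene lists, by dose in cGy and time in hr, in the dose-time set. The erythroid and reticulocyte list is at 1.84 at 450 cGy and -2.32 at 800 cGy at 168 hr.

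In the untreated mice of the sex and treatment set, B cell genes fell and p53 targets rose with dose at 6 hr, in 10 mice per dose over both sexes. The mitotic regulator gene Psrc1 rose by 3.02 ± 0.22, Cdkn1a by 2.72 ± 0.20 (adjusted p = 9.52e-23), Cxcl2 by 2.64 ± 0.49, Ccng1 by 2.16 ± 0.17, Phlda3 by 2.15 ± 0.14 and Mdm2 by 0.85 ± 0.17. Of 36 p53 targets 23 rose and 3 fell (26 and 3 adjusted over the list alone), Polk among them at 1.84 ± 0.14. Ighv14-2 fell (-4.15 ± 0.32), Cd79b (-3.53 ± 0.35), Fcer2a (-2.94 ± 0.17) and Ms4a1 (-2.54 ± 0.39). Of 21 B cell genes 20 fell, and of 8 MHC class II genes 8 (H2-DMb2 -2.49 ± 0.19). Only 5 of 18 mature neutrophil genes rose, and S100a8 (0.19 ± 0.15, adjusted p = 0.168), Alas2 (-0.04 ± 0.05, adjusted p = 0.607) and Cd3e (-0.39 ± 0.15, adjusted p = 0.0535) did not pass. By 24 hr 18 of 18 neutrophil genes and all 18 platelet genes had risen. Rises included Ifit3 at 3.61 ± 0.34, Slfn4 at 3.17 ± 0.26, Saa3 at 2.92 ± 0.51, Lcn2 at 2.42 ± 0.35, Gp5 at 2.13 ± 0.25 and Pf4 at 0.95 ± 0.09. Then Cd8b1 was down (-4.33 ± 0.28), Fcer2a (-3.90 ± 0.17) and Crisp3 (-3.50 ± 0.12), and 20 of 23 T cell genes had fallen.

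In limma 2470 genes passed at 6 hr (936 up, 1534 down), 1262 to 2223 with 1 mouse of every group left out and 7488 with array weights, and 5126 at 24 hr (2271 up, 2855 down). The balance turned with array weights at 6 hr (4305 up, 3183 down) and with centring at 24 hr (3239 up, 2442 down). Of the genes called at 600 cGy and 6 hr in the dose-time set, 93.9% had the same sign here and 51.4% in the small treatment set. The latter share was 46.1 to 67.7% with 1 mouse of every group left out, always with its 0 cGy untreated mouse 10 kept. It was 45.7% with mouse number as a block and 90.7% with array spread as a covariate. With an estimated correlation the camera calls of the p53 (3.06e-05), B cell (2.89e-06), MHC class II (2.88e-04) and T cell (0.0445) lists held at 6 hr. At 24 hr those of the B cell (0.00163), MHC class II (0.00796), T cell (0.0161) and platelet (0.0411) lists held. The neutrophil call at 24 hr (2.73e-12) did not (adjusted p = 0.0802 with an estimated correlation), nor did the interferon call (7.79e-07, then 0.324).

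GCSF alone had few calls. At 24 hr without radiation it raised Ifitm1 by 2.61 ± 0.33, Lrg1 by 2.31 ± 0.35, Igfbp6 by 2.57 ± 0.31 and the neutrophil genes Lcn2 by 2.09 ± 0.35 and S100a8 by 0.96 ± 0.15. It lowered Crisp3 (-0.99 ± 0.12) and Fcer2a (-0.68 ± 0.17), and left Cdkn1a at 0.15 ± 0.20 (adjusted p = 0.655). Of 18 mature neutrophil genes 4 rose over all genes and 10 adjusted over the list alone. Of 16 NK cell genes 0 rose, 0 fell and 15 fell adjusted over the list alone (Ccl5 -0.70 ± 0.19, adjusted p = 0.0535). Of 27 erythroid genes 4 rose, 13 over the list alone (Urod 0.74 ± 0.14). In limma 68 genes passed at 24 hr (41 up, 27 down), 14 to 60 with 1 mouse of every group left out. The count was 2874 with only the groups of the comparison in the fit and 5 without arrays whose Alb was 10 or more, and it reached 4776 with array weights. At 6 hr 0 genes passed in limma, where 283 had an unadjusted p under 0.05 and array weights called 645 (Cd14 0.78 ± 0.38, adjusted p = 0.999). The camera calls of the neutrophil (5.96e-10), NK cell (1.39e-11) and erythroid (3.79e-11) lists at 24 hr gave adjusted p = 0.153, 0.153 and 0.153 with an estimated correlation, and the erythroid call at 6 hr (median -0.32, 2.16e-16) gave 0.158.

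Under GCSF, B cell genes fell and Cdkn1a rose with dose. At 6 hr Cdkn1a rose by 2.42 ± 0.21, Il1r2 by 3.12 ± 0.39, Prok2 by 3.00 ± 0.45 and Mmp8 by 2.66 ± 0.40, and Ighv14-2 fell (-5.10 ± 0.33), Cd79b (-4.38 ± 0.36) and Ms4a1 (-3.89 ± 0.41). There 16 of 18 neutrophil genes rose and 20 of 21 B cell genes fell. At 24 hr Ifit3 rose by 2.98 ± 0.34 and Cdkn1a by 2.37 ± 0.20, and 16 erythroid genes fell and 4 rose, Epb42 (-2.92 ± 0.34) and Trim10 (-2.03 ± 0.24). The slope on dose per 100 cGy differed from that of untreated mice for 2 genes at 6 hr, Ltb4r1 (0.23 ± 0.04, adjusted p = 0.00295) and 0610040J01Rik (0.20 ± 0.04). At 24 hr it differed for 2 genes, Crisp3 (0.19 ± 0.03, adjusted p = 9.06e-07) and Pcp4 (0.08 ± 0.02, adjusted p = 0.0321). These counts ran from 0 to 6 and from 1 to 26 with 1 mouse of every group left out. They were 816 and 266 with array weights and 28 and 33 with array spread as a covariate, and the test recovered 39% and 41% of simulated slope differences of 0.1, so the slopes were not shown to be alike. In limma the GCSF slopes called 6777 genes at 6 hr (3751 up, 3026 down) and 3817 at 24 hr (1644 up, 2173 down). Without arrays whose Alb was 10 or more they called 4231 (1850 up, 2381 down) and 1777, and centring turned the 24 hr balance to 2342 up and 1782 down. The B cell and MHC class II calls held with an estimated correlation at both times (1.71e-04 and 0.00216 at 6 hr, 4.11e-04 and 0.00493 at 24 hr), the neutrophil calls did not (0.236 and 0.0899).

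LPS without radiation raised granule and interferon genes, Cxcl2 and Cxcl10 and lowered lymphocyte genes. At 6 hr the granule genes Ngp, Ltf and Camp rose by 5.73 ± 0.56, 5.31 ± 0.53 and 5.15 ± 0.50. The endothelial lipase gene Lipg rose by 5.57 ± 0.49, Cxcl2 by 4.80 ± 0.53, Cxcl10 by 4.70 ± 0.38 and Ifit3 by 4.07 ± 0.37. Fcer2a fell (-2.78 ± 0.18), Cd3g (-2.79 ± 0.37), Thy1 (-2.56 ± 0.29) and Ccr2 (-2.38 ± 0.37). Of 30 interferon genes 27 rose, of 31 NF-kB genes 24 rose and 1 fell, and 17 of 21 B cell and 18 of 23 T cell genes fell. At 24 hr Ngp rose by 7.10 ± 0.53, Lcn2 by 5.49 ± 0.36, Cxcl2 by 5.07 ± 0.51 and Il1r2 by 5.00 ± 0.39. Then 25 of 38 cell cycle genes rose (Birc5 2.08 ± 0.22), and Ighv14-2 fell (-3.77 ± 0.33) and Crisp3 (-3.46 ± 0.12). Cdkn1a rose with LPS alone, by 0.99 ± 0.22 at 6 hr and 2.09 ± 0.21 at 24 hr. Phlda3 did not pass (0.17 ± 0.15, adjusted p = 0.361, and 0.05 ± 0.15, adjusted p = 0.87) and Ccng1 fell (-0.75 ± 0.19) at 6 hr. In limma 4368 genes passed at 6 hr (1833 up, 2535 down; 2846 up and 2290 down with each array centred), 2074 to 5421 with 1 mouse of every group left out, and 2708 at 24 hr (1140 up, 1568 down), which ran from 1521 without arrays whose Alb was 10 or more to 4768 with array weights. Calls that held with an estimated correlation included interferon (0.00329 and 0.00131), NF-kB (0.00917 and 0.00123), immature granule (2.58e-04 and 1.17e-05), B cell (0.0133 and 1.17e-05), T cell (0.0133 and 0.00123) and cell cycle lists (0.0305 and 0.00123). The platelet call at 24 hr (0.00119) did not hold (adjusted p = 0.416 with an estimated correlation).

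With LPS the dose effects of some genes were weaker or had the other direction. In LPS-treated mice (8 to 10 per dose) at 6 hr the p53 genes still rose with dose (17 of 36, 2 fallen), Ccng1 by 1.99 ± 0.19, Phlda3 by 1.63 ± 0.15 and Cdkn1a by 1.15 ± 0.22. Neutrophil genes fell (12 of 18 mature and 11 of 13 immature): Ltf (-3.91 ± 0.53), Cd177 (-3.28 ± 0.41) and Mmp9 (-3.10 ± 0.36). Ms4a1 (-0.91 ± 0.43, adjusted p = 0.0998) and Cd79a (-0.62 ± 0.27, adjusted p = 0.148) did not pass. At 24 hr Cdkn1a rose by 0.71 ± 0.21, Ms4a1 fell (-3.42 ± 0.41) and 24 of 38 cell cycle genes fell (Bub1 -1.26 ± 0.12). Against untreated mice, the slope per 100 cGy was less negative for Fcer2a (0.50 ± 0.04 at 6 hr, 0.56 ± 0.04 at 24 hr) and Ighv14-2 (0.43 ± 0.08 and 0.52 ± 0.07). It was lower for Il1r2 (-0.57 ± 0.09), Mmp8 (-0.50 ± 0.09) and Mmp9 (-0.49 ± 0.08) at 6 hr. So it was for Slfn4 (-0.49 ± 0.06) and Ifit3 (-0.49 ± 0.08) at 24 hr and for Cdkn1a at both times (-0.24 ± 0.05 and -0.31 ± 0.05). The slopes of Ccng1 (-0.04 ± 0.04, adjusted p = 0.73) and Phlda3 (-0.09 ± 0.03, adjusted p = 0.132) at 6 hr were not shown to differ. The B cell list had 15 genes with a higher slope and none lower, the mature neutrophil list 15 lower and none higher. LPS without radiation had already lowered Fcer2a and raised Ltf at 6 hr and lowered Ighv14-2 at 24 hr, as given above. Whether slopes differed only because the genes started from another level was not tested.

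In limma the slopes differed between LPS and untreated mice for 742 genes at 6 hr (314 higher, 428 lower), 234 to 845 with 1 mouse of every group left out, and for 2101 at 24 hr (929 higher, 1172 lower). Array weights called 1555 and 3529, and at 24 hr 1056 passed without arrays whose Alb was 10 or more. The LPS slopes themselves called 3247 genes at 6 hr (1528 up, 1719 down; 1231 to 3814) and 1595 at 24 hr (388 up, 1207 down; 641 to 1992). For the slope differences the calls of the B cell (5.29e-04), mature neutrophil (0.00447) and T cell (0.0113) lists held with an estimated correlation at 6 hr, and none did at 24 hr (B cell 9.31e-17, then 0.0506; platelet 9.31e-17, then 0.0558). The p53 call for the LPS slope at 6 hr (3.47e-07) gave adjusted p = 0.0681 with an estimated correlation.

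**Figure D5:**
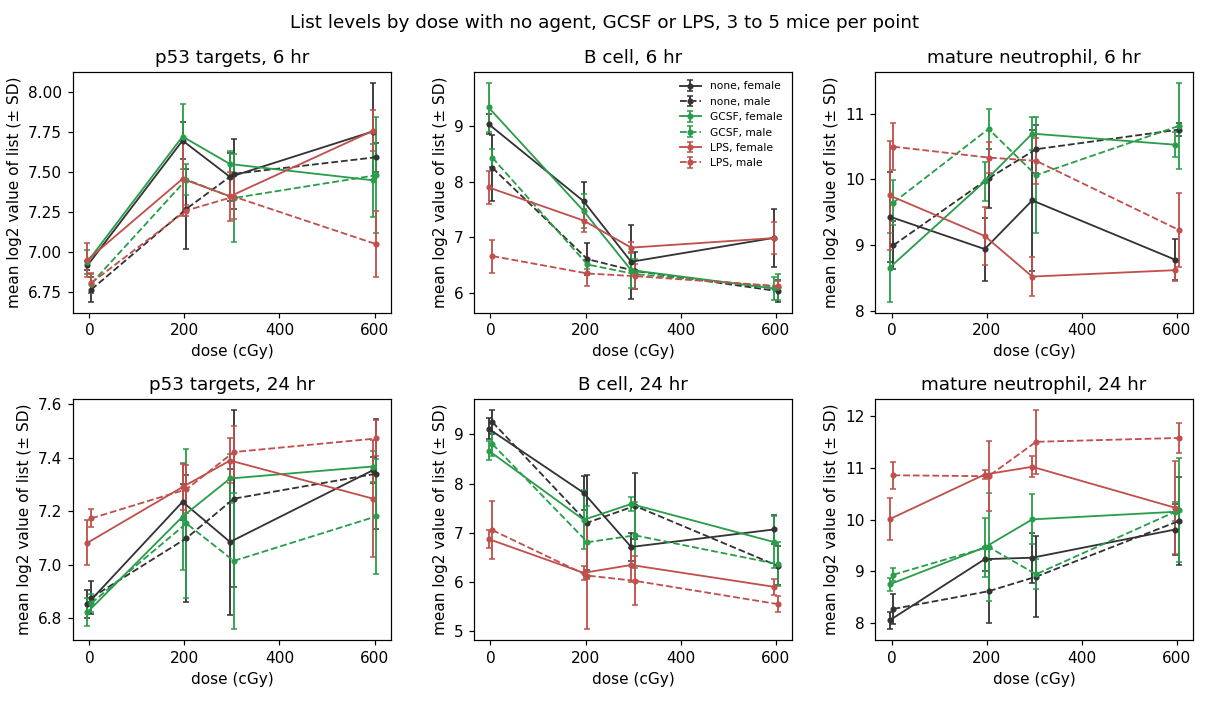
Mean level of the p53 target, B cell and mature neutrophil lists (log2, vertical axes) by dose in cGy (horizontal axes) at 6 and 24 hr in the sex and treatment set, with one colour per agent, one line style per sex, group means of 3 to 5 mice as points and SD as bars. At 6 hr the median of the B cell list at 600 cGy is -2.21 without treatment and -3.00 with GCSF, and that of the mature neutrophil list is -0.96 with LPS.

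Sex was read from its own genes first. Xist averaged 11.47 ± 0.98 (SD, n = 111) in females and 6.69 ± 0.61 (SD, n = 115) in males, and the Y-linked Eif2s3y 3.17 ± 0.46 and 7.00 ± 0.92 (SD). The library labelled female mouse 5 of the untreated 300 cGy group at 6 hr read 5.84 for Xist and 7.77 for Eif2s3y, and that of female mouse 3 of the untreated 0 cGy group at 6 hr read 5.54 and 3.09. The males ranged from 5.05 to 8.31 for Xist and from 4.81 to 8.90 for Eif2s3y. Female mouse 5 thus lay within the male range for both genes, and female mouse 3 for Xist alone. Both were kept as female in the main fits. No fit was run without female mouse 3 alone, which is among the 0 cGy females compared here. At 0 cGy the males stood higher for Eif2s3y (4.21 ± 0.27), Uty (0.82 ± 0.13) and Ly6g6c (1.08 ± 0.23). They stood lower for Xist (-5.06 ± 0.33), the T cell genes Lef1 (-0.95 ± 0.17), Trat1 (-0.86 ± 0.22) and Bcl11b (-0.68 ± 0.18) and the heat shock gene Hsph1 (-1.02 ± 0.23). Of 23 T cell genes 3 were lower in males, and 11 lower and 1 higher adjusted over the list alone. With dose, Cd177 (0.34 ± 0.09 per 100 cGy), Mmp9 (0.34 ± 0.08) and Slc2a1 (0.32 ± 0.07) rose more steeply in males and Mt1 (-0.39 ± 0.10) less. Cdkn1a (-0.08 ± 0.05, adjusted p = 0.437) and Phlda3 (-0.10 ± 0.03, adjusted p = 0.0847) were not shown to differ. In limma 101 genes differed between the sexes (26 higher in males, 75 lower), 3 to 44 with 1 mouse of every group left out 3639 with only the groups of the comparison in the fit and 6139 with array weights. The slopes of 182 genes differed (159 higher, 23 lower), 4 to 134 in the same way, 2683 with array weights and 232 without the 300 cGy female mouse 5. The camera calls of the T cell list at 0 cGy (5.17e-08) and of the mature neutrophil slope (2.21e-14) gave adjusted p = 0.517 and 0.0984 with an estimated correlation.

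The small treatment set, on separate arrays, had p53 and neutrophil genes that rose with dose at 6 hr. Lcn2 rose by 3.39 ± 0.39, Lrg1 by 2.96 ± 0.38, Cdkn1a by 2.89 ± 0.32, Psrc1 by 2.62 ± 0.29, Phlda3 by 1.98 ± 0.25 and Mdm2 by 1.15 ± 0.21, and Ighv14-2 fell (-3.11 ± 0.51) and Fcer2a (-2.63 ± 0.37). Of 36 p53 targets 21 rose, and of 21 B cell genes 10 fell (17 over the list alone), Ms4a1 at -1.08 ± 0.42 (adjusted p = 0.227). GCSF raised Prok2 by 3.14 ± 0.40, Lcn2 by 2.79 ± 0.37, Ngp by 2.59 ± 0.30 and Socs3 by 1.72 ± 0.31. LPS raised Ngp by 6.24 ± 0.30, Acod1 by 5.17 ± 0.30 and Cxcl10 by 5.10 ± 0.24 and lowered the macrophage genes Cd5l (-3.61 ± 0.57), Vsig4 (-3.40 ± 0.58) and C1qa (-2.54 ± 0.53). With LPS 29 of 30 interferon genes rose. In limma 696 genes passed for dose (563 up, 133 down), 339 to 464 with 1 mouse of every group left out. GCSF changed 68 (60 up, 8 down), 16 to 33 in the same way, and LPS 3252 (1263 up, 1989 down). None of the fits with 1 mouse left out dropped the 0 cGy untreated mouse 10, which is described below. The count for GCSF was 2 with only the groups of the comparison in the fit and higher with array weights or array spread as a covariate. Leaving out arrays whose Alb was 10 or more took 5 of the 6 GCSF mice at 0 cGy. The GCSF count of that fit therefore cannot be read as a measure of sensitivity. The count for dose ran up to 1969 with array weights.

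The 0 cGy untreated mouse 10 of this set lay apart from the other controls, at levels of the irradiated untreated mice or beyond. Its mean level of B cell genes was 6.41 (the other 5 controls 8.76 to 9.26, the untreated 600 cGy mice 6.67 to 8.08), of MHC class II genes 8.36 (controls 10.28 to 10.92), of mature neutrophil genes 10.38 (controls 8.20 to 8.78) and of p53 targets 7.71 (controls 6.76 to 6.93, the untreated 600 cGy mice 7.54 to 8.04). The dose trend without treatment and the comparisons of each agent with no treatment use this mouse, and those within an agent share with it only the estimate of the spread. Without it 1158 genes passed for dose (801 up, 357 down), 195 for GCSF (171 up, 24 down) and 3421 for LPS (1269 up, 2152 down), and 56.5% of the genes called at 600 cGy in the dose-time set had the same sign. In the small treatment set with all mice, the camera calls with an estimated correlation of the p53 (4.15e-04) and neutrophil (0.00348) lists for dose and of the interferon list for LPS (3.70e-05) held, and that of the neutrophil list for GCSF (1.15e-15) gave adjusted p = 0.152. There the monocyte list for dose and the immature granule list for GCSF moved up with medians of -0.01 and -0.06 and means of 0.22 and 0.54.

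In the small 7 day set, 150 cGy left B cell genes low and red cell genes high after 168 hr. Crisp3 fell (-3.07 ± 0.37) against the 0 cGy controls, Igkv6-14 (-2.84 ± 0.33), Ighv14-2 (-2.82 ± 0.25) and Cd22 (-2.47 ± 0.18), and 20 of 21 B cell, 8 of 8 MHC class II and 19 of 23 T cell genes fell. Hbb-b2 rose by 3.33 ± 0.45, the erythroid regulator Klf1 by 1.63 ± 0.19 and Rhd by 2.10 ± 0.28, with 24 of 27 erythroid and 6 of 6 globin genes. Cdkn1a rose by 0.45 ± 0.14 and Phlda3 by 0.89 ± 0.21, while Mdm2 fell (-0.89 ± 0.23). Alb rose by 2.73 ± 1.13 (adjusted p = 0.0412) with 15 of 24 hepatocyte genes, and 31 chemosensory, 9 cardiomyocyte and 6 lung genes also rose. In limma 8314 genes passed (4189 up, 4125 down), with 10 mice against 3. The count was 3410 with array spread as a covariate and 5348 with quantile normalisation. The spread of values within an array was 1.90 in the irradiated mice and 2.21 in their controls. None of the camera calls held with an estimated correlation (B cell 5.75e-11, then 0.322; erythroid 5.12e-07, then 0.546).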

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

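In this part the random splits, the gap rule on scores other than p53, the values of mouse 10 and the tests of explanations were chosen only after the results were seen, except the test of the dose labels of the 800 cGy mice. In 4 groups of mice, 1 p53 target score lay far from the others by the gap between neighbouring values over the group's range. The scores were -0.0648 for mouse 1 at 0 cGy and 24 hr of the dose-time set (the other 4 at 0.01 to 0.02) and 0.19 for female mouse 3 given GCSF and 600 cGy at 6 hr (the others at 0.60 to 0.67). They were 0.24 for male mouse 1 given LPS and 0 cGy at 24 hr (the others at 0.30 to 0.32) and 0.69 for mouse 10 at 0 cGy without treatment in the small treatment set (the other 5 at -0.25 to -0.09). Chance gives such a mouse in about 1 in 20 groups, or 5.15 of the 103 tested, so the number of such groups is not above chance. That number does not speak for each mouse, since mouse 10 of the small treatment set, labelled 0 cGy, also had a B cell level of 6.41, under the lowest untreated 600 cGy mouse (6.67), and without it 1158 genes passed for dose against 696 with it. What set this mouse apart was not tested. The same rule, applied after the data had been seen, found 7 groups for the B cell score, 8 for the erythroid and 18 for the hepatocyte score.

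The effect of dose differed between groups of mice in 6 comparisons, each by a test of the difference itself in limma. It differed between times for 11443 genes, between LPS and no treatment for 742 genes at 6 hr and 2101 at 24 hr, between the sexes for 182, and between GCSF and no treatment for 2 genes at 6 hr and 2 at 24 hr. In 1 of 100 splits of the mice, the real one, the result was as large for the differences between times (highest other 263) and between the sexes (highest other 1). For LPS 3 of 100 splits gave as many at 6 hr (highest other 6474) and 2 of 100 at 24 hr (highest other 4221). For GCSF 4 of 100 did at 6 hr (highest other 1336) and 5 of 100 at 24 hr (highest other 324). These splits moved the time, agent or sex of whole mice, so they broke up differences at 0 cGy along with those of slope. They therefore cannot exclude chance for the slopes alone. With 1 mouse of every group left out, the 2 GCSF genes at 6 hr fell to 0 at the lowest and the 182 genes of the sexes to 4. The splits of agent shuffled its label over GCSF, LPS and untreated mice together. A split could thus put LPS mice under the label of GCSF or of no treatment, and LPS alone called 4368 genes at 6 hr and 2708 at 24 hr. Some splits called several times the real count, as for GCSF here, for LPS at 6 hr and for GCSF in the small treatment set. Whether they were splits of this kind was not tested. They are therefore no measure of chance for GCSF against no treatment alone.

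Among the dose trends of the dose-time set, 1 of 100 splits, the real one, gave as many genes at 6 hr (4301, highest other 112), 24 hr (4798, 24), 48 hr (5865, 415), 72 hr (6622, 1258), 120 hr (10208, 5166) and 168 hr (10182, 5634). The real split alone also gave as many for the untreated trends of the sex and treatment set (2470, highest other 1, and 5126, highest other 2809), its GCSF trends (6777 and 5360, 3817 and 543) and its LPS trend at 6 hr (3247 and 51). At 24 hr 2 of 100 splits gave as many genes for the LPS trend (1595, highest other 2835). LPS against no treatment (4368 and 3 at 6 hr, 2708 and 496 at 24 hr) and the small sets (696 and 173 for dose, 3252 and 336 for LPS, 8314 and 7252 for 150 cGy) were reached by the real split alone. GCSF at 24 hr was reached by 3 of 100 (68, highest other 212), GCSF in the small treatment set by 4 of 100 (68, highest other 1842) and male against female by 2 of 100 (101, highest other 134). The splits for GCSF mixed in LPS mice, as given above. For GCSF at 6 hr all 100 splits gave at least the 0 genes of the real one (highest other 5), so chance is not excluded. The share of genes with the same sign was reached by 3 of 100 splits in the sex and treatment set (93.9%, highest other 95.7%) and by 49 of 100 in the small treatment set (51.4%, highest other 90.7%). Such a share was thus rare among splits of the first set alone. Chance is not excluded in either set, since a random split went above each real share.

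The first pattern is the liver transcripts at 120 and 168 hr, where Alb was at least 10 in 30 of 30 mice given 600 cGy or more and in 5 of 40 given 300 cGy or less. After 1050 cGy at 168 hr the list's highest signals, which lie near the top of the scale (14.85) and do not rank the transcripts, were those of Alb (14.55 ± 0.29, SD, n = 5), Apoa1 (14.40 ± 0.29), Hpx (14.13 ± 0.14) and Serpina1b (13.93 ± 0.50), whereas in 0 cGy mice at 6 hr 2 of its 24 genes stood above the median gene, and 0 of the 24 were in a list fixed beforehand. For 120 and 168 hr the values argue against liver tissue taken up at random when the blood was drawn. A two-sided Fisher's exact test on the 30 of 30 and 5 of 40 mice gave p = 1.17e-14. The limit of 10 and the grouping of doses were set after the values were seen. The slope of Alb over all doses in limma, which needs neither, had an adjusted p of 5.86e-15 at 120 hr and 9.24e-11 at 168 hr. At 24, 48 and 72 hr Alb was at least 10 in 23, 26 and 21 of 40 mice. These included 3, 3 and 2 of the 5 mice at 0 cGy, so uptake unrelated to dose stays open at those times. The values also argue against a lower share of blood cell RNA raising every other tissue alike. The heart muscle list had a median of -0.0841 at 1050 cGy and 168 hr, where the liver list had 7.94. This does not bear on a lower share of blood cell RNA that raised liver transcripts alone, which was not tested. Liver tissue taken up more often from mice given a higher dose, which 30 of 30 mice would need, cannot be told apart from liver RNA that reached the blood after the higher doses, because dose and carriage went together in all 30. Dose, which the design names, stays an untested biological explanation.

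The second pattern is the mice labelled 800 cGy at 24 hr, 4 of which had B cell scores of -0.94 to -1.58 where the 450 cGy mice had -2.74 to -2.26. For a swap with the 100 cGy mice at 72 hr, 0 of those 5 mice had a B cell level at or under the highest of the 450 cGy mice at 24 hr (6.91). This cannot decide on a swap, since levels at 24 hr lay on both sides of that limit at 600 cGy (6.01 to 7.75) and 1050 cGy (6.10 to 8.63). Labels of dose that differ from the dose received may explain the pattern. Of the 5 mice labelled 800 cGy, 4 had a T cell score above every 450 cGy mouse. T cell transcripts are part of the lymphocyte pattern itself, so these scores cannot tell a wrong label from a different response. The p53 scores of these 4 (0.05 to 0.19) also lay under those of the 450 cGy mice (0.32 to 0.48). Other doses had such mice too, with B cell scores of -0.55 and -0.70 in 2 of 5 at 1050 cGy and -1.43 in 1 of 5 at 600 cGy, so the pattern is not confined to the 800 cGy label. A different response of the blood to 800 cGy was not tested.

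The third pattern is that calls against 0 cGy were most numerous at low doses at 120 hr (8834 at 100 cGy) and at intermediate doses at 168 hr (9005 at 300 cGy). Array values pulled together in these groups may explain part of it, since 49 of 64 chemosensory receptor genes rose at 100 cGy and 120 hr, where the spread of an array was 1.75 against 2.08 at 0 cGy. Reticulocyte transcripts taking a larger part of the signal may act at 120 and 168 hr, as the erythroid list had a median of 0.89 at 100 cGy and 120 hr. They are argued against at 6 hr, where arrays were narrower too and the erythroid median at 600 cGy was 0.10 with 0 genes past the threshold. A biological change of all these genes with dose stays open and was not tested.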

How the results depend on the processing

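The hepatocyte score and array spread as covariates, the arrays left out for Alb, the 800 cGy mice left out at 24 hr, the 300 cGy female mouse 5 left out and the 0 cGy mouse 10 of the small treatment set left out were chosen only after the results were seen. In this section the GCSF and LPS slopes are the differences of slope from untreated mice, and trends are the slopes within an agent. Array run as a block left 24 of 24 counts within 1.5 times their value, centring and the trended and robust prior 29 of 29 each, the first scan alone 7 of 7, the 800 cGy mice left out 2 of 2 (3578 genes at 24 hr) and the 300 cGy female mouse 5 left out 11 of 11. The causes of the changes below were not tested, except that leaving out mice, arrays or dim genes leaves fewer to test. Without the 0 cGy mouse 10, the small treatment set called 1158 for dose and 195 for GCSF, its share was 56.5%, and its LPS count of 3421 was within 1.5 times. With mouse number as a replicate block, male against female called 168 genes, the slope difference for GCSF at 24 hr 1, the small treatment set 1416 for dose and 192 for GCSF, and its share of the same sign turned to 45.7%. With only the groups of the comparison fitted, GCSF at 24 hr called 2874, male against female 3639, the GCSF slope at 24 hr 1 and GCSF in the small treatment set 2. Without dim genes, whose signal lies nearest to background, the GCSF slope at 24 hr called 0 and the share in the small treatment set was 61.5%. The mean of probe sets gave 5 for the GCSF slope at 24 hr. Quantile normalisation gave 46 for male against female, 5348 for the small 7 day set and a share of 61.4%. Dose on a log2 scale gave 3711 for the untreated trend at 6 hr of the sex and treatment set and 6 and 4 for the GCSF slopes. The F test over 7 differences called 7360 at 24 hr, and genes with a fold of at least 0.5 had a share of 59.6%.

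Array weights, for which the estimation gave a warning, moved 14 of 29 values by over 1.5 times or, for a share, over 5 points, each of them upward. They were 7488 for the untreated trend at 6 hr, 2667 for the LPS trend at 24 hr, 645 and 4776 for GCSF at 6 and 24 hr and 4768 for LPS at 24 hr. The differences of slope from untreated mice had 816 and 266 for GCSF and 1555 and 3529 for LPS. Male against female had 6139, sex by dose 2683, and the small treatment set 1969 for dose, 236 for GCSF and a share of 58.1%. The hepatocyte score as a covariate gave 103 for GCSF at 24 hr and 93 for sex by dose. Without arrays of Alb 10 or more, the counts were 3045 at 24 hr, 5074 at 120 hr, 5174 for the untreated trend at 6 hr, 4231 and 1777 for the GCSF trends, 2094 for the LPS trend at 6 hr, 5 for GCSF and 1521 for LPS at 24 hr. The GCSF slopes then had 0 and 1, the LPS slope at 24 hr 1056, male against female 3 and GCSF in the small treatment set 3478. That last count cannot be read as a measure of sensitivity, because 5 of the 6 GCSF mice at 0 cGy had been left out. With array spread as a covariate the counts were 2341 at 24 hr, 2059 for the LPS trend and 2830 for LPS at 6 hr. They were 170 for GCSF at 24 hr, 28 and 33 for the GCSF slopes and 1408 and 3391 for the LPS slopes. Then male against female had 11, sex by dose 578, the small treatment set 1219 for dose and 613 for GCSF, the small 7 day set 3410, and the shares were 86.5% and 90.7%. That covariate moved the median of all genes at 600 cGy from 0.13 to 0.01 at 6 hr, -0.07 to 0.09 at 48 hr, -0.10 to 0.07 at 72 hr and -0.07 to 0.03 at 168 hr, and that of the small 7 day set from 0.09 to -0.02, and no planned scaling moved it by over 0.1.

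With 1 mouse of every group left out (leave-one-out), counts ran from 2801 to 4786 at 6 hr, 1981 to 6069 at 24 hr, 5325 to 5464 at 48 hr, 5744 to 6520 at 72 hr, 9802 to 10069 at 120 hr, 9834 to 9979 at 168 hr and 11015 to 11315 between times. The untreated trends ran from 1262 to 2223 and 4181 to 5229, those with GCSF from 4531 to 6356 and 2939 to 3691, and those with LPS from 1231 to 3814 and 641 to 1992. GCSF ran from 0 to 0 and 14 to 60, LPS from 2074 to 5421 and 2109 to 2460, the GCSF slopes from 0 to 6 and 1 to 26 and the LPS slopes from 234 to 845 and 1470 to 1962. Male against female ran from 3 to 44, sex by dose from 4 to 134, the small treatment set from 339 to 464, 16 to 33 and 2347 to 3434, and the small 7 day set from 5948 to 8431. The shares ran from 89.2 to 95.4% and from 46.1 to 67.7%, where 46.5% and 46.1% turned the majority. Only the first 5 mice of a group were left out in turn. The ranges of the small treatment set therefore always include its 0 cGy untreated mouse 10, and those of the small 7 day set the 150 cGy mice numbered above 5.

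The balance of directions moved by over 10 points under quantile normalisation for the LPS trend at 24 hr (696 up, 1152 down), GCSF at 24 hr (70 and 24) and sex by dose (119 and 35). Under centring it turned at 24 hr (3141 and 2176), for the 24 hr trends of untreated (3239 and 2442) and GCSF mice (2342 and 1782), for GCSF at 24 hr (31 and 35) and for LPS at 6 hr (2846 and 2290). It moved without turning at 48 hr (3499 and 2220), for the LPS trend at 24 hr (811 and 1051) and for LPS in the small treatment set (1696 and 1716). With array spread as a covariate the balance turned at 120 hr (3913 up, 3252 down) and 168 hr (4176 and 3336), where more genes had fallen without it. Of 2109 values of named genes, quantile normalisation left 1971 on their side of the threshold in the same direction, centring 2073 and array weights 2039, and the run block 1795 of 1798. Reversed were, with the mean of probe sets, Sdc1 at 48 hr (0.0871), 72 hr (0.12) and in the small 7 day set (-0.12) and Pln at 48 hr (0.0111). With quantile normalisation the slope of Mdm2 at 168 hr, positive on the deposited values (fold at 600 cGy now -0.38), Eif2s3y (-0.0115) and Uty (0.0600) at 168 hr, and Ccng1 (0.0116), Cd3e (0.16) and Ifi30 (0.000628) in the small 7 day set reversed. Camera with an estimated correlation lost 216 calls over 624 list tests and left 408 tests as they were. These 408 include tests that passed in neither way, so they are not the number of calls that held. With array run as a block all 624 were as they were, those of the small sets necessarily so, since their fit could hold no run block. Every alternative set before the data were examined was run. The run block has no value in the small sets, which have 1 run each, and leaving out arrays by Alb left some dose groups without mice.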

Other observations

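The tests of the added lists were chosen only after the results were seen. Some genes of the eosinophil, basophil and mast cell list rose with dose at 48 and 72 hr, among them Hdc, the enzyme that makes histamine (2.88 ± 0.30 at 48 hr), Gata2 (2.31 ± 0.24 and 2.83 ± 0.24) and Alox15 (2.41 ± 0.70 at 48 hr). In that list 5 genes rose and 3 fell of 12 at 48 hr and 4 rose and 3 fell at 72 hr (not past the threshold as a list, camera adjusted p = 0.425 and 0.343). Among NK cell genes Klrd1 fell at 48 hr (-2.29 ± 0.33) while Prf1, which encodes perforin, rose (1.38 ± 0.29 at 48 hr and 2.41 ± 0.29 at 72 hr). The monocyte list was split as well, 10 genes risen and 4 fallen at 48 hr, with Cd68 at 2.42 ± 0.31 and Ms4a6c at -2.04 ± 0.28. Of 8 plasma cell genes 2 rose and 3 fell at 48 hr, Jchain being at -1.58 ± 0.34.

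Endothelial genes of the added list rose with dose at 72 hr (5 of 10), with Pecam1 at 3.02 ± 0.30 and Plvap at 2.36 ± 0.24 at 120 hr, and the call of the list (adjusted p = 0.0351) was lost with an estimated correlation (adjusted p = 0.444). Pecam1 had fallen by 168 hr (-0.61 ± 0.30). Of the added lists at 6 hr, 13 of 64 chemosensory receptor, 0 of 24 hepatocyte genes, 1 of 14 tissue macrophage, 2 of 12 cardiomyocyte, 1 of 6 lung epithelium and 2 of 10 endothelial genes rose. The suppressor of cytokine signalling Socs2 rose late, by 3.00 ± 0.31 at 120 hr and 3.40 ± 0.31 at 168 hr, where Socs3 had risen by 3.77 ± 0.24 at 6 hr. The transcriptional repressor gene Bcl6 fell at 120 hr (-2.47 ± 0.26).

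The array spread at 48 hr was 1.89 at 0 cGy against 2.07 to 2.12 in the irradiated groups, and at 168 hr it was 1.77 at 300 cGy and 2.19 at 1050 cGy. In 0 cGy mice given LPS at 6 hr it was 1.89, and 2.03 in those given nothing. In the small treatment set Obp1a (5.24 ± 1.72) and Mucl2 (5.04 ± 1.64) rose with LPS with errors far wider than those of Cxcl10 (5.10 ± 0.24).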
